A study of Mus musculus with 13 samples.

How the data were processed

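The series measured RNA in 13 sequencing libraries from mice of 3 genotypes at the Wfdc15a gene, all at postnatal day 25. Whole testis gave 6 libraries (2 wild type, WT; 1 heterozygous, Het; 3 knockout, KO), each started from 2 ng of total RNA, per the labels' protocols. Round spermatids, the haploid germ cells that follow meiosis, gave 7 libraries (2 WT, 2 Het, 3 KO) of 100 to 200 cells each, sorted by fluorescence after staining of DNA with Vybrant DyeCycle Green, per the labels' protocols. Complementary DNA was made by Smart-seq2, a method that copies whole polyadenylated transcripts and does not record the strand.

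The deposited table lists 30479 genes with their coordinates and, for each library, log2 reads-per-million (RPM). Per the submitters' processing notes, the reads were handled with FastQC 0.11.8, Trim Galore 0.6.6 and HISAT2 2.1.0 on genome build mm10. The program that counted reads per gene and the annotation behind the deposited log2 values are not given in the sources used here. Steps between the low values showed that each deposited log2 value was a whole number of reads divided by a library total, with 0.9 read standing for a gene with no read. Between 99.797% and 99.997% of the values in a library came out whole within 0.01 read. Every one of the 13 libraries has its column, and 0 other columns of per-sample values were present. The 13 mitochondrial genes in the table had no read in any library, so transcripts encoded by mitochondria were not analysed here.

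The total to which a library was scaled ranged from 7375270 reads (KO replicate 1) to 18438704 reads (WT replicate 1) in testis, and from 10825690 (Het replicate 2) to 20927428 (KO replicate 1) in round spermatids. At these depths a gene with no read could still be present at up to 0.143 to 0.407 RPM, the level of 3 reads, which covers counting error only. Smart-seq2 reads carry no molecular identifiers and are not independent molecules, and 60.7% to 63.5% of values from 2 to 50 reads were even, so a fragment may often stand for a pair of reads. No library pair agreed within sampling noise: the smallest chi-square per degree of freedom between libraries of one group was 10.5. Of the gene symbols, 96.82% were found in GENCODE M21, and 99.15% of those lay at identical coordinates, so lengths and exons were taken from that annotation.

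The log2 values were turned back into RPM, with genes at 0 reads set to 0. Genes with at least 1 RPM in at least 2 libraries of a fit were tested on log2(RPM + 1), a scale that understates changes of low genes. The tests were limma's linear model with empirical Bayes moderation along the intensity trend (lmFit and eBayes, limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Each cell type was fitted apart with its 3 genotypes; WT round spermatids against WT testis, and the difference of the KO effect between cell types, came from a single fit of all 13 libraries. Wfdc15a was tested by exact two-sided permutation as well. Because the deposited unit is not a count, limma on log2 values was the main test, and voom on the recovered reads was an alternative.

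The comparisons, tests, 35 gene lists, rule for named genes and most alternatives were chosen before the data were examined. The lists cover cell types of the testis, stages of spermatogenesis, proteases and their inhibitors, immune and stress pathways, ribosomal protein and HOX genes, X-linked genes, and genes within 1 Mb of Wfdc15a. They were tested with limma's camera at a preset correlation of 0.01 between genes, where at least 5 members were measured, and again with an estimated correlation. A further planned test, limma's fry, asks whether the members of a list change together, without setting them against other genes. Named genes were, for each KO against WT comparison, the 10 with the largest change in each direction among genes past the threshold whose groups did not overlap, leaving out predicted genes and pseudogenes. The other comparisons named 5 per direction, a shortfall was filled by the smallest unadjusted p, and for each list up to 4 members with the smallest unadjusted p could be named. Where another gene is named, the text says so. Some genes that the rule would name are not reported here.

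After the data were seen, the libraries were found to fall into 2 sets in both cell types. Fits with the set as a covariate, fits within a set, and corrections for gene span or transcript length (a loess with span 0.5 removed from each library) were added, and their results depend on that choice. Further alternatives were a pseudocount of 0.1 RPM, the log2 values as deposited, no filter, a mean of at least 5 RPM, and centred or quantile-normalized libraries. Others were library quality weights, a replicate block, a fit of all libraries, an adjusted p under 0.1, a change of at least 2-fold, and leaving out each library in turn.

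The fits were tested on simulated data in which 200 of the genes were changed. With no set difference simulated, KO against WT recovered 53.7% of genes changed 4-fold in testis and 97.0% in round spermatids. With the set difference put in as estimated from the real libraries, it recovered 0% in testis and 74.6% in round spermatids at 4-fold, and the fit with the set as a covariate recovered 62.7% and 100%. In that simulation the list of round spermatid markers was also shifted, by 1 log2 unit. In testis camera on KO against WT missed the shifted list (adjusted p = 0.223) and called 12 others of the 32 lists. In round spermatids it called the shifted list and 8 others of 31. With the set as a covariate it called the shifted list and 1 other in each cell type. The simulated noise was drawn for each gene apart, and the set acted alike in every genotype, as that fit assumes. In the real data the estimated correlation between genes of a list reached 0.94, for Sertoli cell markers in testis. The simulation thus does not show how camera or that fit behaves with such correlation. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.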

Results

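Gene expression was compared between Wfdc15a knockout (KO), heterozygous (Het) and wild-type (WT) mice at postnatal day 25, when the first wave of spermatogenesis has reached round spermatids. Wfdc15a belongs to the WAP four-disulfide core family, whose members include secreted protease inhibitors, and the stated aim was its function in spermatogenesis. Whole testis was profiled in 2 WT, 1 Het and 3 KO libraries and sorted round spermatids in 2 WT, 2 Het and 3 KO libraries. Library totals ran from 7375270 to 18438704 reads in testis and from 10825690 to 20927428 reads in round spermatids. The labels do not say whether libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

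Wfdc15a lies on chromosome 2 from 164198863 to 164200130 of mm10, on the minus strand, with 3 exons and a protein-coding sequence that starts in exon 1. In testis it was at 212 and 207 RPM in the WT libraries, 48.4 RPM in the Het library and 116, 36.8 and 44.3 RPM in KO replicates 1 to 3. In round spermatids it was at 267 and 234 RPM in WT, 65.0 and 71.5 RPM in Het and 97.9, 67.4 and 48.1 RPM in KO. The KO mean was 65.8 ± 43.8 RPM (SD, n = 3) against 209.8 ± 3.69 RPM (SD, n = 2) in WT testis, and 71.1 ± 25.1 RPM (SD, n = 3) against 250.6 ± 22.8 RPM (SD, n = 2) in WT round spermatids. On the log2(RPM + 1) scale KO minus WT was -1.85 (SE 0.55, limma adjusted p = 0.122) in testis and -1.86 (SE 0.28, limma adjusted p = 0.121) in round spermatids, and Het minus WT was -2.09 (adjusted p = 0.216) and -1.86 (adjusted p = 0.0626). None of these 4 differences passed the threshold in the fit chosen beforehand. Against WT and Het together, the exact two-sided permutation p for KO was 0.2 in testis, where 0.1 is the smallest the design allows, and 0.314 in round spermatids, where it is 0.0286. With the set as a covariate, a fit added after the data were seen, KO against WT and Het together was -0.55 (SE 0.28, limma adjusted p = 0.398) in testis and -0.69 (SE 0.20, adjusted p = 0.170) in round spermatids. KO minus WT did pass with library quality weights (-2.35 in testis and -1.92 in round spermatids), with the set as a covariate, where it is KO replicate 1 minus WT (-0.85 and -1.34), without KO replicate 1 (-2.35 and -2.12) and, in testis, in a fit of all 13 libraries (-1.85). Without KO replicate 1, KO and WT lie in different sets, and in testis the weighted value is the same -2.35. In the set-covariate fit, set 2 minus set 1 for Wfdc15a was -1.80 (SE 0.28) in testis and -1.42 (SE 0.20) in round spermatids. Apart from the set-covariate calls, these calls are thus not separate from the set. The set-covariate values compare KO replicate 1 with WT inside set 1, and rest on a single KO library per cell type. Reads of Wfdc15a were present in every KO library, the labels do not describe the allele, and the level in Het was as low as in KO, so the gene's level does not separate KO from Het libraries. Wfdc15b, the neighbouring family member, was at no more than 0.799 RPM in any library.

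**Figure D1:**
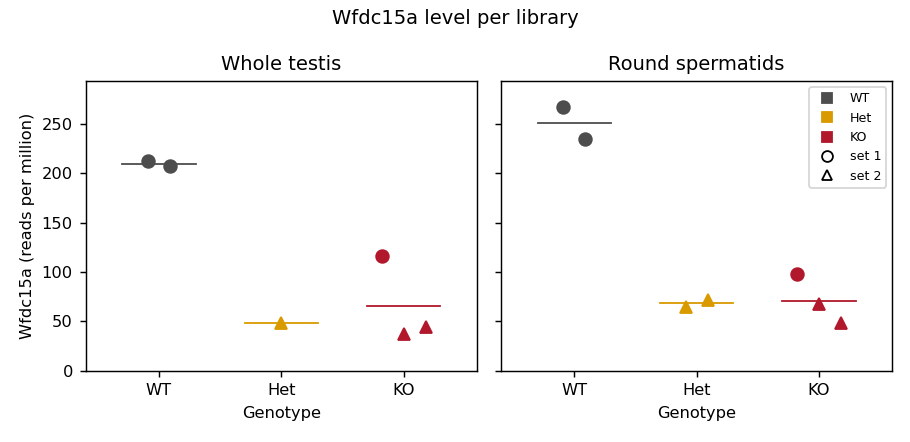
Wfdc15a in RPM in each library, by genotype, in whole testis and round spermatids; lines are group means, and circles and triangles are the samples of set 1 and set 2. WT libraries sit between 207 and 267 RPM and all Het and KO libraries between 36.8 and 116 RPM.

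Libraries of both cell types separated first along a line that was not genotype. Both WT libraries and KO replicate 1 (called set 1) stood against the Het libraries and KO replicates 2 and 3 (called set 2) on the leading principal component, which held 71.6% of the variance in testis and 55.6% in round spermatids. The spermatid chromatin gene Prm1 was at 1106, 546 and 268 RPM in the 3 testis samples of set 1 and at 26.2, 32.1 and 16.7 RPM in those of set 2. Clu, abundant in Sertoli cells, was at 16.3, 17.5 and 2.44 RPM in the first and at 1149, 1159 and 1204 RPM in the second. Dcn, a matrix proteoglycan of stromal cells, was at no more than 0.478 RPM in the 3 round spermatid samples of set 1 and between 177 and 299 RPM in the 4 of set 2. The samples also differed in technical measures: the 10 most abundant genes took 8.05%, 8.11% and 4.95% of reads in the testis samples of set 1 and 3.16%, 3.05% and 3.13% in set 2, and in round spermatids 4.74%, 4.45% and 4.92% against 3.84% to 3.97%. The labels record no batch, and the sets were drawn from the data. As set 1 held all WT libraries and set 2 all Het libraries, a difference between WT and Het can be told apart from one between sets only through the KO libraries, which stood in both, and only if the set acted alike in every genotype.

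**Figure D2:**
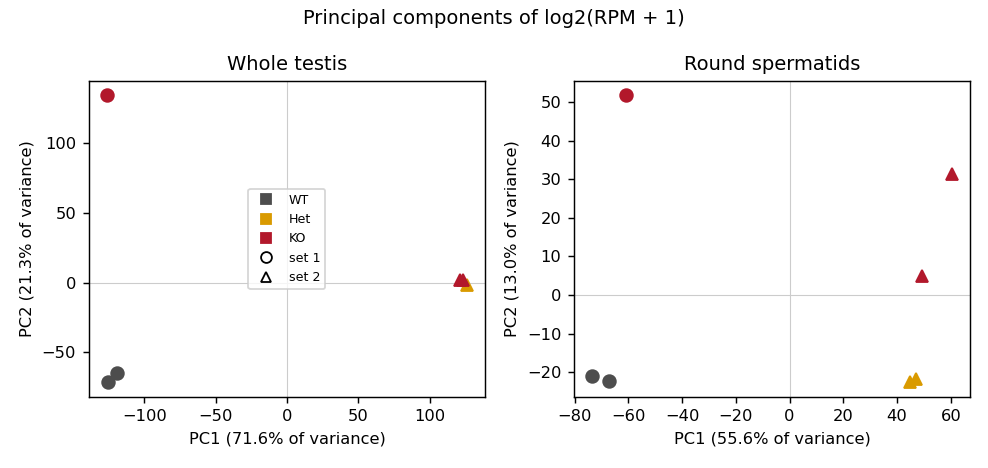
Principal components of log2(RPM + 1) for the 6 testis and 7 round spermatid libraries, coloured by genotype, with circles for set 1 and triangles for set 2. The first component, with 71.6% and 55.6% of the variance, separates the sets, and KO libraries lie on both sides.

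In whole testis, KO libraries showed higher values than WT for Sycp1, a synaptonemal complex protein of meiotic cells (+3.87, SE 0.35), and the nuclear RNA Malat1 (+4.36, SE 0.37), in log2 units with 3 KO and 2 WT libraries. Values were also higher for the stromal proteoglycan Dcn (+4.999, SE 0.52), the testis globin Adgb (+5.36, SE 0.61) and the RNA-binding protein Atxn2l (+3.68, SE 0.28). Lower values were found for Ldhc, the lactate dehydrogenase of male germ cells (-1.56, SE 0.21), the respiratory complex I subunits Ndufb5 (-2.27, SE 0.30) and Ndufa9 (-1.65, SE 0.24), the glutaredoxin Glrx3 (-1.48, SE 0.23) and the transcobalamin receptor Cd320 (-1.91, SE 0.29). Further named genes were Srrm1 (+3.56), Dop1a (+4.14), Prrc2a (+3.56), Akap12 (+3.47) and Slf1 (+3.53), and Rtraf (-1.80), Yif1b (-2.14), Hacd1 (-2.21), Dapp1 (-2.08) and Tmbim7 (-1.84). None of these passed the test. The Het library stood on the KO side of WT for all of these genes, so the values do not single out KO. Mean log2(RPM + 1) in WT, Het and KO was 4.19, 7.79 and 8.06 for Sycp1 and 14.05, 12.61 and 12.49 for Ldhc. The median of all genes stood at +0.63 in this comparison; relative to it Sycp1 was at +3.24 and Ldhc at -2.19. Of 18570 genes tested, limma called 0 (smallest adjusted p = 0.0710, 4380 at an unadjusted p under 0.05), and voom also called 0, while library quality weights gave 12535 genes, a fit of all 13 libraries 4153, the set as a covariate 6992 and an adjusted p under 0.1 gave 1535. Without KO replicate 1, the KO library of set 1, the count was 11976, and KO and WT then differ in set as well.

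Among the gene lists in testis, ribosomal protein genes were lower in KO, with a median of -1.74 over 72 members and values such as Rpl9 (-1.56, SE 0.26). None of the 72 passed over all genes and 53 passed adjusted over the list alone; camera gave an adjusted p of 2.71e-32, and with an estimated correlation the adjusted p = 0.634. Interstitial stromal cell markers were higher, with a median of +2.17 over 17 members, among them the collagens Col1a2 (+4.72, SE 0.66) and Col3a1 (+5.999, SE 1.04); 10 of the 17 passed adjusted over the list alone and none over all genes. For them the camera adjusted p was 4.78e-04 and 0.859 with an estimated correlation. Beta-defensins, antimicrobial peptides also made in the male tract, were lower in all 7 measured members, with a median of -1.36, and Defb30 stood at -2.53 (SE 0.66). None of the 7 passed over all genes or adjusted over the list alone, and the camera adjusted p was 9.47e-04 and 0.634 with an estimated correlation. Markers of Sertoli cells (+2.40, 27 of 30 positive), Leydig cells (+2.14, 19 of 21 positive) and meiotic spermatocytes (+1.58, 29 of 39 positive) and histone-to-protamine genes (-0.96, 11 of 19 negative) did not pass camera (adjusted p = 0.0875, 0.0875, 0.129 and 0.0990), and 0, 5, 12 and 7 members passed adjusted over the list alone. Relative to the median of all genes the ribosomal, stromal and beta-defensin lists stood at -2.37, +1.54 and -1.99, and they kept their sign with centred and with quantile-normalized libraries. Within set 1 (KO replicate 1 minus WT) the medians were -0.91, +1.52 and -1.50, and within set 2 (KO minus the Het library) they were +0.43, +0.27 and +0.29, so the ribosomal and beta-defensin directions did not hold in both.

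Protease and protease-inhibitor genes, named in the study's title, gave no list past camera's threshold in testis. Testis serine proteases had a median of -0.11 over 28 members, with Prss58 at -4.38 (SE 1.001) and Prss45 at -1.74 (SE 0.36), and the serine protease Htra1 at +3.42 (SE 0.63); 3 members passed adjusted over the list alone. WFDC and neighbouring Kunitz-type inhibitors had a median of -0.80 over 10 members, with Wfdc3 at -1.69 (SE 0.53). Serpins, cystatins and other inhibitors had a median of +1.40 over 28 members, with Serpinf1 at +3.13 (SE 0.69) and Cst8 at -2.47 (SE 0.55), and 8 passed adjusted over the list alone. ADAM and ADAMTS metalloproteases stood at +1.02 over 35 members and matrix metalloproteases and cathepsins at +1.70 over 18, with Ctsd at +3.30 (SE 0.81). The camera adjusted p values of the 5 lists were 0.0875, 0.0875, 0.507, 0.248 and 0.0990. Of the immune lists, interferon-stimulated genes had a median of +0.95 (adjusted p = 0.447), inflammatory cytokines and chemokines +0.81 (0.445) and complement +1.17 (0.445), against +0.63 for all genes, and the cytokine median turned negative with centred libraries. In round spermatids the first 3 lists had medians of +0.04, -0.28 and +0.48, with camera adjusted p values of 0.710, 0.710 and 0.103, and the first median turned negative with centred libraries.

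In round spermatids, KO libraries had lower values than WT for the Y-box proteins Ybx3 (-1.62, SE 0.24) and Ybx2 (-1.16, SE 0.22), which bind stored mRNA in male germ cells. Lower values were also found for Psme4, the proteasome activator PA200 (-1.05, SE 0.16), for Smcp, a sperm mitochondrial capsule protein (-1.20, SE 0.23), and for Fgf14, an intracellular fibroblast growth factor homologue (-1.56, SE 0.29). They had higher values for the monoamine oxidase Maoa (+3.37, SE 0.49), the splicing factor Sf3b3 (+2.82, SE 0.43), the proton pump subunit Atp6v1h (+1.60, SE 0.25), the kinesin Kif2c (+1.33, SE 0.22) and the intraflagellar transport gene Wdr19 (+1.13, SE 0.19). Other named genes were Gtpbp10 (+3.41), Washc4 (+2.71), Dock5 (+3.35), Ankrd27 (+1.46) and Stx12 (+2.81), and Cd72 (-1.43), Klf4 (-1.52), Erich6 (-1.34), Cpxm2 (-2.21) and Snrpf (-1.07). None passed the test with 3 KO and 2 WT libraries. Smcp was lower still in Het: its mean log2(RPM + 1) was 7.57 in WT, 6.03 in Het and 6.37 in KO. The named higher genes were all above WT in Het too. Maoa, for one, was at 0.37 in WT, 3.74 in Het and 3.74 in KO. Ybx3 was at 8.53, 7.01 and 6.91, while Fgf14, at 6.22, 6.20 and 4.66, stayed near WT in Het. Against WT and Het together with the set as a covariate, Smcp stood at -0.25 (SE 0.20), Ybx3 at -0.67 (SE 0.17) and Maoa at +1.27 (SE 0.41). In that fit Psme4 stood at -0.80 (SE 0.10) and Fgf14 at -1.53 (SE 0.21). Of 18075 genes, limma called 0 (smallest adjusted p = 0.121, 3813 at an unadjusted p under 0.05) and voom called 0. With centred libraries the count was 4, with library quality weights 5706, with the set as a covariate 89, and without KO replicate 1 it was 5514.

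Of the lists in round spermatids, 13 passed camera's preset correlation, and none held with an estimated correlation, where every adjusted p of these lists was 0.604. Ribosomal protein genes had a median of -0.87 (72 members, adjusted p = 8.35e-11; 41 passed adjusted over the list alone), with Rps27 at -1.54 (SE 0.37). Germline genes controlled by DNA methylation had a median of +0.60 (25 members, adjusted p = 8.71e-05; 14 passed adjusted over the list alone), among them the RNA helicase Ddx4 at +1.24 (SE 0.26). Markers of some other cell types were higher: Sertoli cells +1.13 (26 members, adjusted p = 4.15e-04; 2 adjusted over the list alone), stromal cells +2.71 (17 members, adjusted p = 5.72e-04; 0) and Leydig cells +0.95 (20 members, adjusted p = 0.00515; 0). Endothelial cell markers stood at -0.24 (9 members, adjusted p = 0.258). Meiotic spermatocyte markers stood at +0.61 (39 members, adjusted p = 0.00756; 10 adjusted over the list alone), with Hormad1, a meiotic chromosome axis protein, at +1.41 (SE 0.25). Round spermatid markers stood at -0.24 (37 members, adjusted p = 0.00515; 0 adjusted over the list alone). Genes of the exchange of histones for protamines stood at -0.40 (19 members, adjusted p = 0.0259; 7 adjusted over the list alone), with Prm1 at -2.01 (SE 0.55) and Prm2 at -1.31 (SE 0.38).

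Of the remaining 5 lists past the preset threshold in round spermatids, the first 3 were matrix metalloproteases and cathepsins (+1.16, adjusted p = 0.00386; 0 of 17 adjusted over the list alone), antigen presentation by MHC class I (+0.72, adjusted p = 0.00515; 3 of 15) and the unfolded protein response (+0.61, adjusted p = 0.00515; 0 of 24). The others were steroid and sterol synthesis (+0.60, adjusted p = 0.0242; 0 of 24) and ADAM metalloproteases (+0.36, adjusted p = 0.0411; 1 of 34). No member of the 13 lists passed over all genes. All 13 kept their sign with centred and quantile-normalized libraries. Within the samples of set 1 the medians were -0.19 for ribosomal protein genes, -0.18 for Sertoli cell markers, -0.11 for stromal markers and -0.03 for meiotic markers, and within set 2 they were +0.25, +0.75, +0.73 and -0.07. For the histone-to-protamine list they were -0.58 and -0.30. Its members Prm1 and Prm2 differed between the KO libraries of set 2: Prm1 was at 13.1 RPM in KO replicate 3 and 54.2 RPM in KO replicate 2, against 49.1 and 42.8 RPM in Het, and Prm2 at 35.0 and 97.4 RPM against 111 and 89.5 RPM. Dcn, of the stromal list, was at 206 and 177 RPM in Het and 0.478 RPM in KO replicate 1.

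**Figure D3:**
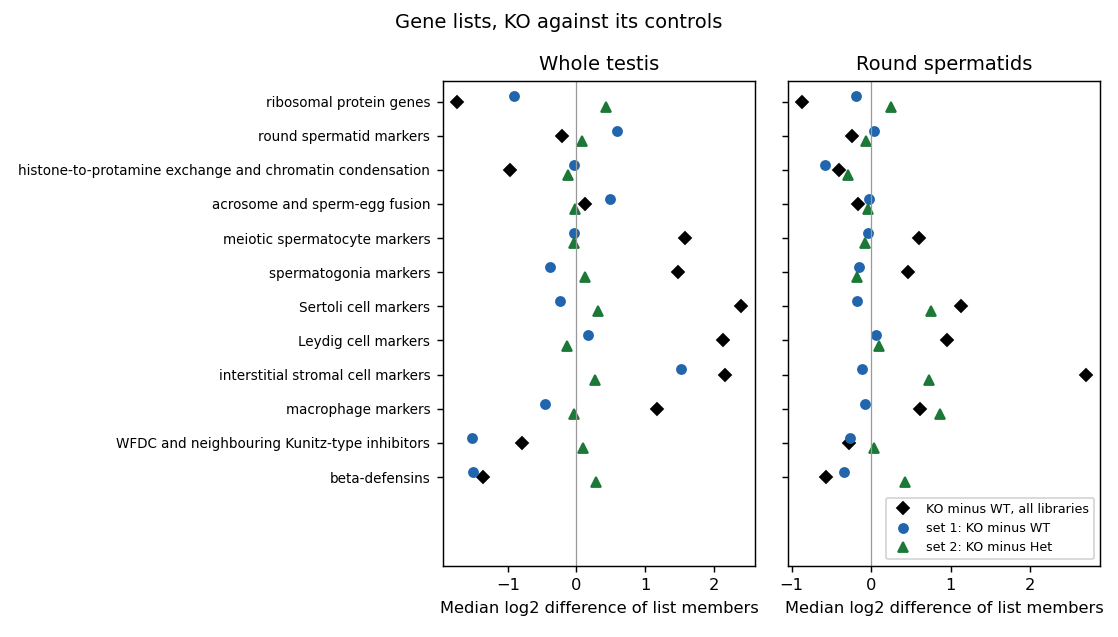
Median log2 difference of the members of 12 gene lists in whole testis and round spermatids: black diamonds are KO minus WT over all libraries, blue circles KO replicate 1 minus WT (set 1), green triangles KO replicates 2 and 3 minus Het (set 2). Ribosomal protein genes stand at -1.74 and -0.87 over all libraries and at +0.43 and +0.25 within set 2.

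Against WT and Het libraries together, KO round spermatids had lower values of Ptprc, the leukocyte phosphatase CD45 (-2.31, SE 0.39), the glutamate receptor Grm5 (-2.02, SE 0.34), the adhesion protein Opcml (-1.71, SE 0.33), Fgf14 (-1.55, SE 0.26) and the netrin receptor Unc5c (-1.78, SE 0.34), with 3 KO and 4 other libraries. Higher values were found for Lxn (+1.33, SE 0.38) and Slc38a4 (+1.30, SE 0.38). In testis the named genes with the smallest p in each direction were Pth1r (+1.88, SE 0.50) and Slc43a1 (+1.74, SE 0.50), and Myo16 (-2.38, SE 0.64) and Lrrtm4 (-2.01, SE 0.59), with 3 libraries on each side and a median of all genes of +0.29. Relative to that median Pth1r stood at +1.59 and Myo16 at -2.67. Limma called 0 genes in either cell type (smallest adjusted p = 0.890 in testis and 0.989 in round spermatids; 477 and 824 at an unadjusted p under 0.05), and voom called 0 in both. In testis, 5903 genes passed in set 1 alone, where KO is 1 library, and 11 in set 2 alone; in round spermatids 186 and 4 did. With library quality weights 13096 passed in testis.

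With the set as a covariate, a fit added after the data were seen, 19 genes fell and 0 rose in KO round spermatids against WT and Het together (2072 at an unadjusted p under 0.05; 8 called by voom). Psme4, on chromosome 11, fell by 0.80 (SE 0.10, limma adjusted p = 0.00393), from 685 and 646 RPM in WT and 521 and 492 RPM in Het to 346, 330 and 292 RPM in KO. Fgf14 fell by 1.53 (SE 0.21, adjusted p = 0.00393), with 76.5 and 70.7 RPM in WT, 62.1 and 84.2 RPM in Het and 26.2, 32.0 and 17.1 RPM in KO. Opcml fell by 1.79 (SE 0.29, adjusted p = 0.0195), Ptprc by 2.37 (SE 0.39, adjusted p = 0.0195), Grm5 by 2.00 (SE 0.35, adjusted p = 0.0340) and Ptprd, a receptor phosphatase, by 1.27 (SE 0.22, adjusted p = 0.0340). Ptprc was low throughout, at 4.85 and 2.16 RPM in WT, 6.19 and 5.17 RPM in Het and at most 0.142 RPM in KO. Named after their values were seen, the others included the ubiquitin ligase scaffold gene Cul3 (fell by 0.92) and the sperm genes Zan (fell by 1.09) and Fsip2 (fell by 0.67). In 14 of the 19 every KO library lay below every WT and Het library. For Fsip2 and Epc2 this did not hold: KO replicate 2, at 549 and 21.1 RPM, lay above a WT library at 481 and 15.9 RPM, and KO replicate 1 was lowest, at 255 and 1.72 RPM. They also included Pde4d, Muc16, Epc2 and the predicted genes Gm10800 and Gm10801, which lie next to each other on chromosome 2 and may share reads. After a correction for gene span 8 of the 19 were still called, among 36 genes of which 25 were higher and 11 lower, so the one-sided direction of the calls did not hold. Psme4 (-0.55) and Ptprc (-2.12) kept their call, as did Epc2 and predicted genes such as Gm10800 and Gm10801. Fgf14 (-0.91, limma adjusted p = 0.0712), Opcml (-1.06, 0.172), Grm5 (-1.42, 0.134) and Ptprd (-0.40, 0.528) lost it. After a correction for transcript length 2 of the 19 were still called, while the median of the 17 others went from -1.22 to -1.01 (SE 0.22 before and after), so the loss of calls does not by itself show that length carried the difference. Those with the longest transcripts moved further: Muc16 (25437 nt) went from -1.05 to -0.49 (SE 0.18), Fsip2 (21116 nt) from -0.67 to -0.16 (SE 0.11) and Zan (16481 nt) from -1.09 to -0.64 (SE 0.20). The correction thus took away most of the fall of Fsip2, while Zan kept more of its fall than it lost. The count was 0 without either Het library or with no filter, 3 without KO replicate 1, 4 without KO replicate 3, 5 without either WT library and 105 without KO replicate 2. In testis the same fit called 0 genes (smallest adjusted p = 0.398, 2130 at an unadjusted p under 0.05; voom 0) and 7123 without the Het library.

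**Figure D4:**
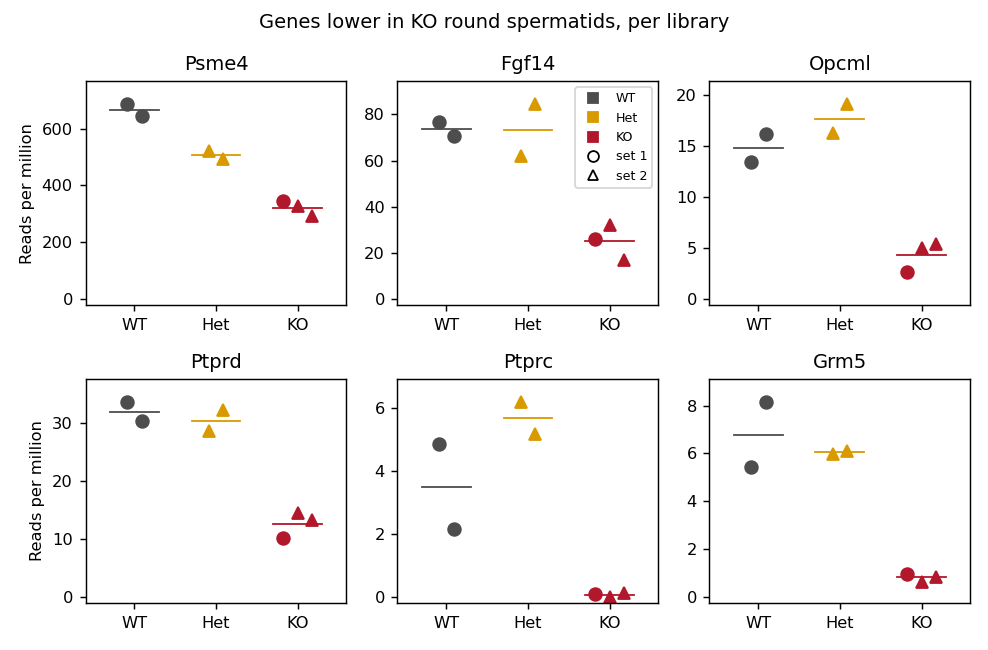
RPM of 6 genes in each round spermatid library, by genotype; lines are group means, and circles and triangles are the samples of set 1 and set 2. Psme4 lies between 492 and 685 RPM in WT and Het libraries and between 292 and 346 RPM in KO.

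Lists in the same set-covariate fit of round spermatids that passed camera were Sertoli cell markers (+0.42, adjusted p = 9.98e-05), ribosomal protein genes (+0.06, adjusted p = 5.40e-04), stromal markers (+0.25, adjusted p = 0.0113) and histone-to-protamine genes (-0.31, adjusted p = 0.0113). Others that passed were germline genes (+0.12, adjusted p = 0.0122), macrophage markers (+0.41, adjusted p = 0.0178) and matrix metalloproteases and cathepsins (+0.26, adjusted p = 0.0193). Prm1 stood at -0.90 (SE 0.30) and Prm2 at -0.83 (SE 0.23), though in KO replicate 2 neither was below both Het libraries, and the macrophage gene Lyz2 at +0.99 (SE 0.40), while Ptprc, in the same list, fell. In testis stromal markers (+1.01, adjusted p = 0.00328), immediate-early and heat-shock genes (+0.88, adjusted p = 0.00679), sperm flagellum genes (+0.29, adjusted p = 0.0257) and WFDC inhibitors (-0.73, adjusted p = 0.0281) passed. Within set 1, where KO is 1 library, their medians were +1.52, +1.47, +0.56 and -1.53, and within set 2 they were +0.27, +0.19, -0.07 and +0.10. That library, testis KO replicate 1, had 15435 genes with a read against 20115 to 22587 in the other testis libraries, and a score of 134 against -71.6 to 1.92 on the component with 21.3% of the variance. With an estimated correlation every adjusted p in round spermatids was at least 0.539 and every one in testis at least 0.913, so none held.

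Het against WT addresses the effect of losing a single copy. In round spermatids (2 Het, 2 WT) Het had higher values of Bbs2, a ciliary transport gene (+2.08, SE 0.30), Dock5 (+3.92, SE 0.56), Sf3b3 (+3.15, SE 0.47), the replication factor Wdhd1 (+3.71, SE 0.56) and the cytokinesis gene Anln (+1.75, SE 0.27). It had lower values of Pet100 (-2.46, SE 0.37), Afm (-3.90, SE 0.60), Afp, the alpha-fetoprotein gene (-3.80, SE 0.60), Rbakdn (-1.74, SE 0.28) and Smcp (-1.54, SE 0.25). In testis (1 Het, 2 WT) Dcn stood at +5.29 (SE 0.70), Dop1a at +4.80 (SE 0.59), Malat1 at +4.24 (SE 0.50) and Ndufb5 at -2.72 (SE 0.40). The median of all genes was +0.23 in round spermatids and +1.02 in testis, and relative to it Smcp stood at -1.77 and Dcn at +4.27. Limma called 0 genes in both (smallest adjusted p = 0.177 in testis and 0.0626 in round spermatids; 3674 and 4542 at an unadjusted p under 0.05), and voom called 0 in both. Het and WT lay in different sets, and with the set as a covariate, where the set effect is taken from KO replicate 1 against KO replicates 2 and 3, 3572 genes passed in testis and 0 in round spermatids. Without KO replicate 1, which lends its spread to the fit, 10440 genes passed in testis and 4739 in round spermatids, and with library quality weights 10636 and 4815. A fit of all 13 libraries gave 2912 in testis. In round spermatids centring gave 440 genes, quantile normalization 837, and omission of KO replicate 3 gave 1156.

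WT round spermatids (n = 2) differed from WT testis (n = 2) in genes of the acrosome and the tail. Spaca1, needed for acrosome formation, rose by 3.59 (SE 0.31, limma adjusted p = 3.49e-04), the hyaluronidase Spam1 by 3.999 (SE 0.37, adjusted p = 3.60e-04), and Akap3, a scaffold of the fibrous sheath, by 3.31 (SE 0.26, adjusted p = 3.49e-04). The largest rises under the rule for named genes were Prr27 (+6.11), Adgb (+5.53), Tasor2 (+5.26), Nutm1, a spermatid chromatin regulator (+4.80), and the nonsense-mediated decay factor Upf3b (+4.65), and the largest falls were Tex101 (-4.50), Commd9 (-4.35), Rpl39 (-4.25), Wfdc10 (-4.0001) and Rassf1 (-3.95). Each of these named rises was lower in WT testis than in the Het testis library and in the mean of KO testis. On the log2(RPM + 1) scale Prr27 was at 0.99, 6.11 and 5.30 in WT, Het and KO testis, and Adgb at 0.81, 6.55 and 6.17. The size of these rises thus rests on the WT testis libraries. For Spaca1, Spam1 and Akap3 the difference of round spermatids from testis was also smaller in KO than in WT. KO minus WT of that difference was -2.01 (SE 0.40), -2.52 (SE 0.47) and -2.02 (SE 0.33). The size of their rises thus depends on which libraries are compared as well. Insl3, the Leydig cell hormone, fell by 3.94 (SE 0.66, adjusted p = 0.00354), while Wfdc15a did not pass (+0.25, SE 0.49, adjusted p = 0.845). The median of all genes was +0.20, and relative to it Prr27 stood at +5.91 and Tex101 at -4.70. Limma called 2305 of 20085 genes, 1825 higher and 480 lower, and voom called 2520. The split was 727 higher and 455 lower with centred libraries and 1106 and 751 with quantile normalization. The count was 670 and 674 without a WT round spermatid library, 820 and 1161 without a WT testis library and 5966 without testis KO replicate 1. With library quality weights it was 6221 and with the set as a covariate 7480.

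By list, sperm flagellum genes had a median of +0.97 in WT round spermatids over WT testis (21 higher and 1 lower of 56; 31 adjusted over the list alone; camera adjusted p = 1.52e-07), and this call held with an estimated correlation (adjusted p = 0.0452). No other list did. Acrosome genes had a median of +1.28 (21 of 48 higher; 27 adjusted over the list alone; adjusted p = 2.25e-07, and 0.204 with an estimated correlation), and round spermatid markers +1.33 (13 of 37 higher; 18 adjusted over the list alone; adjusted p = 3.41e-06, and 0.337). ADAM metalloproteases, several of which act in sperm, stood at +0.73 (10 of 35 higher, also adjusted over the list alone; adjusted p = 0.00299, and 0.791). Ribosomal protein genes stood at -1.47 (30 of 72 lower; 40 adjusted over the list alone; adjusted p = 1.11e-32, and 0.204). Beta-defensins stood at -2.53 (4 of 7 lower, also adjusted over the list alone; adjusted p = 0.00138, and 0.204), with Defb19 at -3.28 (SE 0.44). WFDC inhibitors stood at -1.24 (2 of 11 lower, also adjusted over the list alone; adjusted p = 1.95e-04, and 0.291). Sertoli cell markers stood at -0.76 (2 of 30 lower, also adjusted over the list alone; adjusted p = 0.00160, and 0.909), and Leydig cell markers at -0.87 (1 of 21 lower, also adjusted over the list alone; adjusted p = 0.00178, and 0.899). Genes within 1 Mb of Wfdc15a stood at -0.22 (2 lower and 1 higher of 56; 2 adjusted over the list alone; adjusted p = 0.00758, and 0.899). The second adjusted p in each bracket is that with an estimated correlation.

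The KO minus WT difference itself differed between round spermatids and testis for 428 genes in limma's interaction term, 59 higher and 369 lower in round spermatids, and voom called 334. Adgb stood at +5.36 in testis KO, and its difference between cell types was -5.22 (SE 0.72, adjusted p = 0.0168). Kcnq1ot1, an imprinted noncoding RNA (-5.67, SE 0.63), and Ccdc138 (-4.73, SE 0.65) were lower in the same sense, and Cd320 (+2.25, SE 0.31) and the adhesion gene Cntn1 (+3.50, SE 0.72) were higher. In testis the Het library stood on the KO side of WT for all of these genes. On the log2(RPM + 1) scale Adgb was at 0.81 in WT, 6.55 in Het and 6.17 in KO, and Cd320 at 9.68, 7.62 and 7.77. KO replicates 2 and 3 also differ from WT in set, while KO replicate 1 does not. The SD over all KO testis libraries was 0.50 for Adgb and 0.24 for Cd320, far less than their distance from WT. As the Het library stood on the KO side too, these values do not single out KO. The median of all genes in this term was -0.48, and relative to it Adgb stood at -4.74 and Cntn1 at +3.98. With centred libraries 0 genes passed and with quantile normalization 1 did, while a mean of at least 5 RPM gave 849, library quality weights 6946 and the set as a covariate 5275. The count was also 0 without testis WT replicate 1 or without either WT round spermatid library, and lay between 39 and 169 without any of the other libraries except testis Het (443) and testis KO replicate 1 (6211). Ribosomal protein genes (+0.97, adjusted p = 1.16e-19), testis serine proteases (+0.54, adjusted p = 0.009998), beta-defensins (+1.23, adjusted p = 0.009998) and WFDC inhibitors (+0.75, adjusted p = 0.0156) passed camera in this term. With an estimated correlation the adjusted p values were 0.729, 0.240, 0.493 and 0.999. Of their members 1, a serine protease, passed over all genes, and 3 of that list passed adjusted over the list alone.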

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

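Tests of the explanations weighed here were all chosen after the results were seen, while the test of the difference between cell types was planned.

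The KO minus WT difference in round spermatids minus that in testis passed limma's interaction test for 428 genes. Among the named genes it was positive for Cntn1 (+3.50), Capns2 (+2.69), Dapp1 (+2.30), Cd320 (+2.25) and Ubash3a (+2.05). It was negative for Kcnq1ot1 (-5.67), Adgb (-5.22), Ccdc138 (-4.73), Fam76b (-4.56) and Taok3 (-4.49). For all of these named genes the Het testis library stood on the KO side of WT, so the values do not single out KO. Kcnq1ot1, for one, was at 0.28 in WT, 4.92 in Het and 4.81 in KO testis on the log2(RPM + 1) scale. With centred libraries 0 genes passed. No group held 4 or more libraries, so no library was tested for standing apart from its group.

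The first pattern is the split of libraries by set in both cell types. Genotype alone is argued against by the KO libraries: over genes, which are not independent replicates, KO replicate 1 correlated with KO replicates 2 and 3 at 0.743 and 0.737 in testis and 0.933 and 0.920 in round spermatids, below the 0.976 and 0.973 and the 0.962 to 0.967 of KO replicates 2 and 3 with Het. With the WT libraries KO replicate 1 correlated at 0.961 and 0.961 in round spermatids, where the WT libraries correlated at 0.963. In testis it correlated with them at only 0.822 and 0.830, against 0.957 between the WT libraries. Its distance from KO replicates 2 and 3 in testis thus need not come from the set alone. The set difference inside KO followed Het minus WT at 0.609 and 0.685, which restates how the sets were drawn, and at 0.568 and 0.646 with the transcript length trend removed, so that trend is not the whole source. Fewer spermatids and more cells of other types in set 2 go with medians, set 2 minus set 1, of +3.42 for Sertoli, +3.30 for Leydig and +3.19 for stromal markers and -0.64 for round spermatid markers in testis, and of +3.18 for stromal and -0.29 for round spermatid markers in cells sorted by a DNA stain, which should leave out diploid cells. Other cell-type lists in the sorted cells were uneven. Sertoli and Leydig markers stood at +1.60 and +1.69, macrophage markers at +0.72 (4 of 19 risen, 2 fallen) and endothelial markers at +0.02 (1 of 9 risen). Such a change in cell content cannot be told apart from a difference in library preparation: added cells lower a gene no further than the loss of spermatids, and ribosomal protein genes, at -1.85 (quartiles -2.33 and -1.07) and -1.16 (quartiles -1.47 and -0.485), overlapped round spermatid markers (quartiles -1.29 and +0.65, and -0.728 and -0.128).

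The second pattern is that Wfdc15a was as low in Het as in KO libraries. The library set stays open as an explanation: 6.70% of 2912 genes of similar level were as low in Het minus WT testis and 1.57% of 2667 in round spermatids, and 38.1% and 11.5% of the 257 and 243 with short transcripts, a choice made afterwards. An effect of genotype cannot be told apart from it, as KO minus Het within set 2 was -0.26 in testis and -0.26 in round spermatids, and Het and WT can be compared across sets only through KO. No error was computed for KO minus Het itself. The SE of KO against WT and Het together, with the set as a covariate, was 0.28 in testis and 0.20 in round spermatids. Within set 1, KO replicate 1 minus WT was -0.85 and -1.34, and 28.0% and 0% of the genes with short transcripts were as low. This rests on a single KO library per cell type.

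The third pattern is the 19 genes lower in KO round spermatids with the set as a covariate. A trend with gene span as the whole source is argued against for 8 genes still called after its removal (median -1.601 before, -1.46 after, SE 0.28), though 36 genes were then called, 25 higher and 11 lower; for the 11 others, whose median went from -1.09 to -0.70 (SE 0.20) as their call ended, it cannot be told apart. With the transcript length trend removed 2 genes were still called (median -1.43 before, -1.32 after), and the 17 others went from -1.22 to -1.01 (SE 0.22), a smaller change with a similar error, so length stays open for them. Of the 18 splits that keep the number of KO libraries per set, 1 gave as many genes, the real one (19, highest other 0); 18 splits cannot give a share under 0.05. No call can therefore be attributed to genotype alone, and the Wfdc15a knockout may be one source among these.

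For KO against WT and Het together without the set, the real count was 0, which all 10 splits in testis and all 35 in round spermatids must reach, so the splits say nothing about chance. The highest other counts, 9617 and 6166, came from the split by set, which points to a structure of the samples. With the set as a covariate in testis the real count and that of all 9 splits was 0, which decides nothing either.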

How the results depend on the processing

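The set covariate, the fits within a set and the span and length corrections were chosen after the data were seen; the other settings were planned.

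Genes past the threshold with library quality weights were 12535 (testis KO vs WT), 5706 (round spermatid KO vs WT), 13096 (testis KO vs WT and Het), 10636 and 4815 (Het vs WT in testis and round spermatids), 6221 (WT round spermatids vs testis) and 6946 (difference between cell types). With the set as a covariate they were 6992, 89, 3572 for testis Het, 7480 and 5275, where KO vs WT rests on KO replicate 1 alone, and 19 for round spermatid KO vs WT and Het. Within set 1 alone KO vs WT and Het gave 5903 and 186, and within set 2 alone 11 and 4. A fit of all 13 libraries gave 4153 for testis KO and 2912 for testis Het. Centring gave 4 for round spermatid KO, 440 for Het, 1182 for WT round spermatids vs testis and 0 for the difference; quantile normalization gave 837 for Het and 1 for the difference. A mean of at least 5 RPM gave 849 for the difference. An adjusted p under 0.1 gave 1535 (testis KO), 1668 (round spermatid Het), 1107 (difference) and 83 (set covariate), as a looser threshold must.

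The 19 genes of the set-covariate fit became 3 with a pseudocount of 0.1, 1 with log2 values as deposited, 0 with no filter, 5 with centring, 7 with weights, 8 with voom, 36 (25 higher, 11 lower) with the span trend removed and 2 with the length trend removed.

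Leaving out each library gave 0 to 11976 genes for testis KO, 0 to 5514 for round spermatid KO, 0 to 10440 for testis Het and 0 to 4739 for round spermatid Het, the highest without KO replicate 1. It gave 670 to 5966 for WT round spermatids vs testis, 0 to 6211 for the difference, 0 to 7123 for the testis set-covariate fit and 0 to 105 for that of round spermatids. A lone sample left in a group is assumed to vary like the others.

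Wfdc15a kept its sign throughout. In testis KO vs WT it passed with weights (-2.35), in the fit of all libraries (-1.85) and with the set covariate (-0.85), and ranged from -2.35 to -1.53 without single libraries; in round spermatids it passed with weights (-1.92) and the set covariate (-1.34), and ranged from -2.12 to -1.61. Both set-covariate values are KO replicate 1 minus WT. Against WT and Het it passed with weights in testis (-2.30) and within set 1 (-0.85 and -1.34), again with 1 KO library, and did not pass with the set covariate over all KO libraries (-0.55 and -0.69).

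The 3 lists past camera's threshold in testis became 11 with no filter, 10 with centring, 13 with quantile normalization, 19 with weights, 5 against WT and Het, 0 with an estimated correlation and 3 to 17 without single libraries. The 13 in round spermatids became 7 with voom, 7 against WT and Het, 7 with the set covariate and 0 with an estimated correlation.

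With the replicate block, genes were 152 for testis KO, 1127 for testis Het and 1589 for round spermatid Het, and lists were 14 in testis; the block moved no other count by over 1.5 times. The numbers were not taken to pair samples: WT and KO of one number correlated at 0.0156 in testis and 0.0403 in round spermatids. Between the cell types own numbers correlated at -0.0231 for WT and at 0.517, 0.306 and 0.423 for KO, where KO replicates 1 and 3 but not 2 (0.368 with another) correlated best with their own number. The 0.517 of KO replicate 1 is the set difference inside KO, which both cell types share, so these values cannot tell pairing apart from the set.

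Of 2172 alternatives for 120 named results, 1713 kept their side of the threshold, 174 lost the call, 285 gained it and 0 reversed. Where the construction does not show it, the cause was not tested. Depth limits genes under 0.143 to 0.407 RPM, the level of 3 reads.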

Other observations

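The principal component of round spermatids and the span test below were examined after the data were seen.

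In KO against WT, none of the following lists passed camera in the cell type for which a median is given. In testis, medians were +1.47 for spermatogonia markers, +1.61 for peritubular myoid cells, +0.90 for endothelial cells, +1.18 for macrophages, +0.12 for lymphocytes, +1.57 for immediate-early and heat-shock genes, +1.16 for p53 targets and +1.78 for haemoglobin and erythroid genes, against +0.63 for all genes. They were +1.85 for steroid and sterol synthesis, +1.18 for germline genes, +0.89 for the unfolded protein response, +0.71 for MHC class I, +0.75 for the sperm flagellum, +0.12 for the acrosome and -0.21 for round spermatid markers. Fry, taken for change in one direction, did pass in testis for immediate-early and heat-shock genes (fry adjusted p = 0.00347). It also passed there for the sperm flagellum (fry adjusted p = 0.00881). Within set 2 the medians of these lists were +0.19 and -0.07. HOX genes stood at +0.38 (7 members, adjusted p = 0.423), X-linked genes at +1.22 (685 members, adjusted p = 0.0875) and genes within 1 Mb of Wfdc15a at +0.34 (52 members, adjusted p = 0.256). In round spermatids HOX genes stood at -0.24 (adjusted p = 0.125), X-linked genes at +0.26 (adjusted p = 0.0876) and genes within 1 Mb of Wfdc15a at +0.02 (adjusted p = 0.473). The endothelial, lymphocyte, unfolded protein, MHC class I, flagellum and acrosome medians and those of HOX genes and of genes near Wfdc15a turned negative in testis with centred libraries, and that of genes near Wfdc15a in round spermatids did so with centred (-0.04) and quantile-normalized libraries (-0.03).

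Testis KO replicate 1 stood apart from the other testis libraries on the component with 21.3% of the variance. Lars2, a mitochondrial leucyl-tRNA synthetase, was at 2385 RPM there and between 130 and 186 RPM in the other testis libraries, and Trim30a was at 3927 RPM against 14.8 to 166 RPM. Both genes were chosen after their values were seen.

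In round spermatids the component with 13.03% of the variance had scores of 51.7, 4.81 and 31.3 in KO and from -22.7 to -21.0 in WT and Het. The component was picked for these scores, so no test is given.

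A hypothesis was that the 19 genes lower in KO round spermatids are lower in KO testis too, as 12 of them span over 100 kb. In testis 9 were lower and 10 higher, with a median of +0.13, and at an unadjusted p under 0.05 there were 5 lower and 1 higher, which decides nothing. As this leaves open whether testis has the pattern, gene span as its source cannot be weighed. The fifth of genes with the longest span stood at a median 0.0101 above that of the others in testis, while in round spermatids it had a median of -0.28 against -0.02.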
